A study of Oncopeltus fasciatus with 9 samples.

How the data were processed

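RNA was measured in eggs of the milkweed bug Oncopeltus fasciatus, aged 48 to 64 h and kept at 25 degrees Celsius, with 100 eggs in each of 9 samples. Per the labels' protocols, total RNA was extracted with Trizol, treated to digest DNA and purified on an RNeasy column, and TruSeq libraries were sequenced on an Illumina HiSeq. Per the submitters' processing notes, the tools were Trimmomatic 0.36, HISAT2 2.0.5, featureCounts 1.5.2 and DESeq2, whose version is not given in the sources used here.

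The deposited table holds raw counts of read pairs for 19793 transcript models, with no normalization. Per the file headers, featureCounts summed the exon pieces of each model without using strand, and its options for reads that overlap several models or map to several places were off. Reads from exons shared by isoforms, from overlapping models or from near-identical copies were therefore left out of these counts, and reads from antisense partners cannot be told apart. Levels of gene families with close copies, such as the defensins, are uncertain for this reason. The genome build behind the scaffold coordinates is not given in the sources used here beyond the annotation's name, OGSv1.2. Gene names, exon numbers and positions, counted from 1, come from the deposited annotation, in which 1678 models had a name and 47 were marked as edited by the authors. The authors also deposited DESeq2 tables of log2 fold changes and adjusted p-values for septic and for sterile injury against naive eggs.

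All further values were computed from the counts. Library totals ran from 11768529 to 16068460 counts, models of ribosomal RNA took 0.346% to 0.418% of the reads, and the 10 most abundant models took 6.21% to 6.65%. The 3 groups with 3 samples each were compared pairwise in 1 fit of all 9 libraries with edgeR 4.0.16 (R 4.3.3), using TMM factors, which ran from 0.993 to 1.01, and genes kept by filterByExpr. That filter left 13224 models holding 99.9% of the reads, so that 1 read was worth less than 0.1 CPM (edgeR's counts scaled by the TMM-adjusted library total). The test was edgeR's quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors belong to log2 fold changes, and SD to CPM over 3 libraries. Intervals at 95% and floors of 3 counts over a group cover counting error only. Pairs of samples of a group differed by 4.17 to 30.0 in chi-square per degree of freedom, so no library was a copy of another within sampling noise.

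Gene lists were matched to the annotation's names, and each list with at least 3 tested members was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over 21 lists per comparison. Calls of members are given over all tested genes and adjusted over the list alone. The list of models edited by the authors was chosen in the study of these samples and is not independent evidence. The list for serpins matched no model, and no result exists for it.

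Genes were named by a rule. In each comparison it took named genes past the threshold with a mean of at least 1 CPM and with the 3 libraries of one group all above those of the other, up to 10 that rose and 5 that fell. It added up to 15 called list members with the smallest p, for each list without a call up to 2 members with the highest mean CPM, and up to 2 unnamed genes in each direction. For lists without a call, members were named in the comparison of septic with naive eggs. Genes called in the paired fit, and other genes said to be so, were chosen after their values were seen. The groups, the tests, the lists, the naming rule and the alternatives first listed below were fixed before the data were examined.

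The labels give each group the replicate numbers 1 to 3 without saying what a number stands for. Deviations of the libraries from their group means over 8903 genes with a mean log2 CPM of at least 3 correlated at 0.309 to 0.879 between samples with the same number in 2 groups, in all 9 such pairs, and at -0.836 to 0.644 between other numbers. Samples with number 3 correlated at 0.718 to 0.879 and those with number 2 at 0.686 to 0.786. Those with number 1 correlated at 0.309 to 0.444, within the range of 0.207 to 0.644 between numbers 1 and 2. The correlations therefore set replicate 3 apart but do not show that the samples with number 1 belong together. Pairing by number is thus an assumption. A second fit with the replicate number as a block, called the paired fit, is given where it changed a call or a count. The common biological coefficient of variation was 14.7% without the block (6 residual degrees of freedom) and 6.69% with it (4 residual degrees of freedom).

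The steps were tested on simulated counts with 200 changed genes in each comparison, 100 of them changed 2-fold and 100 changed 4-fold. For septic against naive the test recovered 69% of the 2-fold and 92% of the 4-fold changes among 13121 genes, with 11 false calls among 172. For sterile against naive these values were 66% and 90% among 13108 genes, with 3 false calls among 159, and for septic against sterile 65% and 87% among 13116 genes, with 6 among 158. With the replicate block, on counts simulated with replicate effects, 83%, 88% and 83% of the 2-fold changes were recovered in the same order. Of the 4-fold changes 98%, 98% and 96% were recovered. Of these calls 23 of 204, 17 of 203 and 15 of 194 were false, above the 5% that the threshold allows. Calls made only in the paired fit are therefore less certain. Without the block the share was also above 5% for septic against naive. The counts simulated for the fit without the block held no replicate effect, so its error on paired samples was not tested.

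The alternatives were DESeq2's size factors, upper-quartile factors or library totals in place of TMM, no filter beyond 1 read, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, a fit of only the 6 samples compared, the replicate block, edgeR's glmTreat against a 1.5-fold change, and leaving out each library in turn. For the lists they also included camera with an estimated correlation and fry. After the data were seen, a fit of the libraries of replicates 1 and 2 alone and camera with both the block and an estimated correlation were added. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).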

Results

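Gene expression was measured by RNA sequencing in whole eggs of the milkweed bug Oncopeltus fasciatus, a plant-feeding true bug. Naive eggs were left alone, sterile eggs were pricked with a clean tungsten needle, and septic eggs were pricked with a needle carrying live bacteria of Escherichia coli and Micrococcus luteus. Each of the 3 groups had 3 replicates, which are separate samples of 100 eggs. The labels say no more about their origin, so p-values measure only the spread between these samples. Library totals were 11768529, 15880712 and 16068460 counts in naive, 15785120, 13140773 and 15062337 in sterile and 13815584, 14931509 and 12830480 in septic replicates 1 to 3.

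The comparison of septic with naive eggs addresses which genes of the egg respond to an infected wound, and among genes with a name the largest rises were in genes for antimicrobial peptides, small secreted proteins that kill microbes. Defensin-2 like (OFAS005103) was at 50.7 ± 13.8 CPM (SD, n = 3) in septic eggs and at 0.0206 ± 0.0356 CPM in naive eggs, where 1 read was counted in all. Defensin-2 Like (OFAS005105), on the same scaffold, was at 52.0 ± 15.5 CPM against 0.0411 ± 0.0712 CPM, from 2 naive reads. Riptocin (OFAS012870), an antimicrobial peptide by its name, rose from 0.433 ± 0.119 to 47.2 ± 35.5 CPM, and its septic replicate 3 stood above the other septic libraries. Of the melanization genes 2 rose with them: Tyrosine 3-monooxygenase (OFAS007495), which makes DOPA from tyrosine, rose from 1.05 ± 0.267 to 20.9 ± 3.88 CPM, and laccase 1 (OFAS011306), a copper oxidase, rose from 0.749 ± 0.0993 to 8.97 ± 1.58 CPM.

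The count ratio of septic to naive eggs was 2187 (95% interval 392 to 86431) for OFAS005103 and 1119 (309 to 9249) for OFAS005105, and both genes had an adjusted p of 6.2e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The same test gave log2 fold changes of 4.30 (SE 0.23) for Tyrosine 3-monooxygenase and 3.56 (SE 0.19) for laccase 1, also at an adjusted p of 6.2e-05 (Benjamini-Hochberg). Riptocin rose by 6.73 (SE 0.70) on the log2 scale, with an adjusted p of 0.00413 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without naive replicate 1 its adjusted p in that Benjamini-Hochberg adjusted edgeR test was 0.0526, and over all alternatives it ran from 1.1e-12 to 0.0526. In each of these genes the 3 septic libraries lay above the 3 naive ones, a condition of the naming rule and so no added support. On the annotation's scaffolds, OFAS005103 has 3 exons at 551426 to 553340 of scaffold 344, and OFAS005105 has 3 exons at 568939 to 571026 of the same scaffold. Riptocin has 3 exons at 254888 to 259795 of scaffold 1136, Tyrosine 3-monooxygenase 11 exons at 421250 to 455381 of scaffold 603 and laccase 1 12 exons at 208464 to 235081 of scaffold 1066. Reads that fit close copies equally well were not counted, so the defensin levels are uncertain. Of the 41 genes called in any comparison, 0 had an exon overlapping another model.

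**Figure D1:**
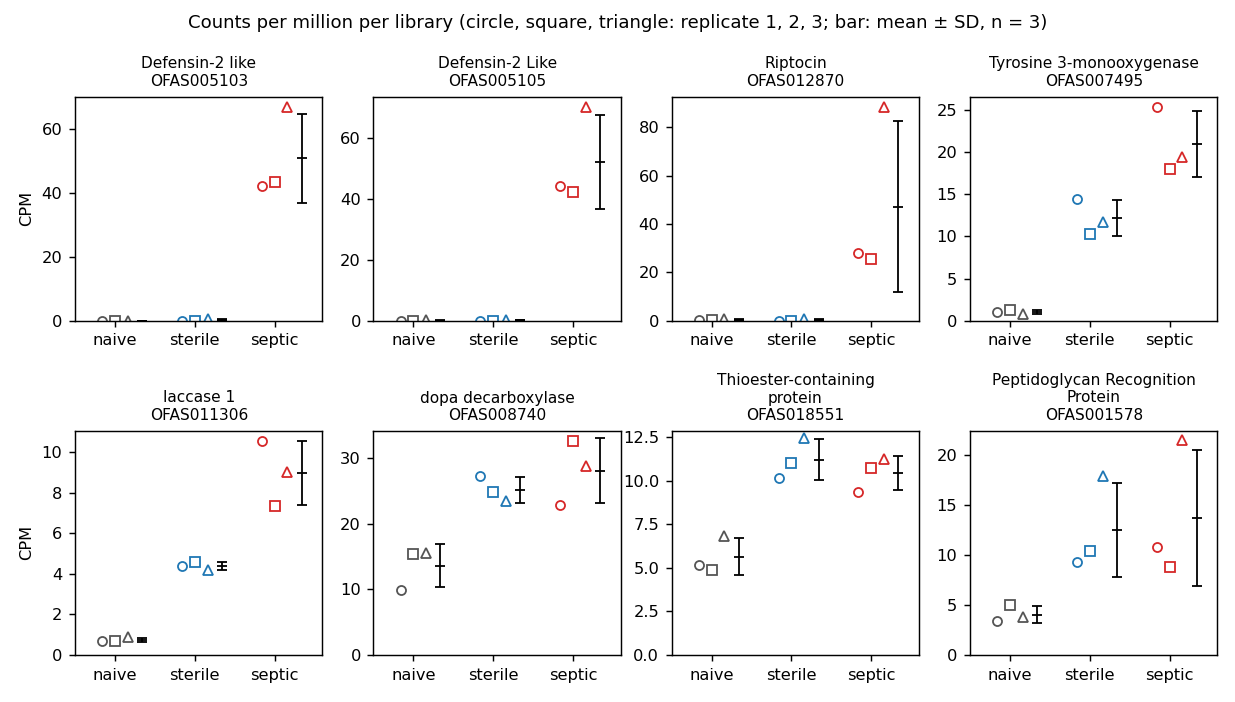
CPM (vertical axes from 0, one panel per gene model) in each of the 9 libraries of naive, sterile and septic eggs. Circles, squares and triangles are replicates 1, 2 and 3, and bars are the mean ± SD of 3 libraries. Both Defensin-2 models and Riptocin sit near 0 in naive and sterile eggs, with septic means of 50.7, 52.0 and 47.2 CPM. Tyrosine 3-monooxygenase has means of 1.05, 12.2 and 20.9 CPM in naive, sterile and septic eggs.

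In all, 38 of 13224 tested genes were higher in septic than in naive eggs and 0 were lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the smallest rise was 2.25-fold. At an unadjusted p under 0.05, 244 genes were higher and 218 lower, together fewer than the 661 that chance alone gives. This fit keeps the variation shared by same-numbered samples in its spread (coefficient of variation 14.7%, against 6.69% with the block). The shortfall is therefore no measure of a lack of change. DESeq2 called 67 higher and 7 lower, and edgeR with the replicate block called 80 higher and 15 lower and kept all 38. Of the 38 genes, 30 had no name in the annotation. Those with the largest fitted rise were OFAS013885, at least 734-fold higher at 51.1 ± 21.1 CPM, and OFAS013883, at least 585-fold higher at 40.6 ± 10.8 CPM, both with 0 naive reads. Each has 1 exon on scaffold 1289, at 236780 to 237049 and at 212275 to 212632. Their adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00129 and 0.00323. The order of the rises is not settled at so few naive reads. Unnamed OFAS009139, with 1 naive read, had a count ratio of 1465 (95% interval 263 to 57911). The count of 38 fell to 18, 24 and 24 without naive replicate 1, 2 or 3, to 24 without sterile replicate 1, and to 20 and 22 without septic replicate 1 or 3.

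The other called genes with a name are not on the antimicrobial peptide or melanization lists. The bumetanide-sensitive sodium-(potassium)-chloride cotransporter (OFAS027083), which carries ions across cell membranes, rose from 4.65 ± 1.22 to 17.1 ± 4.58 CPM, and Drosophila Integral Protein (OFAS000084) rose from 0.850 ± 0.169 to 2.96 ± 0.747 CPM. Both had an adjusted p of 0.0429 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Both calls were lost without naive replicate 1, 2 or 3, sterile replicate 1 or 3, or septic replicate 1 or 3, with only the 6 samples compared, with glmTreat and with replicates 1 and 2 alone, and the highest adjusted p of that Benjamini-Hochberg adjusted edgeR test among the alternatives was 0.209 and 0.267. A model named unknown secreted protein (OFAS012858), chosen after its values were seen because its mean was under 1 CPM, had 34 reads in septic and 2 in naive eggs, a ratio of 17.9 (95% interval 4.59 to 154). Its adjusted p was 0.0195 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the call was lost without naive replicate 1 or 2, sterile replicate 1, or septic replicate 1, 2 or 3, at up to 0.106, and with the 6 samples compared, replicates 1 and 2 alone or DESeq2, at up to 0.155.

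Among the gene lists, antimicrobial peptides and melanization stood out in septic eggs. Of 9 tested antimicrobial peptide models 3 rose, and 4 adjusted over the list alone. The list ranked up by camera with an adjusted p of 1.7e-14, and with an adjusted p = 0.0992 with an estimated correlation. Its median log2 fold change was 0.83, also with the model that had no naive read set at its lower bound. The added model, Defensin (OFAS005104, 2 exons at 558433 to 559624 of scaffold 344), had 26, 18 and 39 reads in septic replicates 1 to 3 and 0 in naive and sterile eggs, at least 29.1-fold above naive. Its adjusted p was 0.122, and 0.00686 with the replicate block, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 7 tested genes of melanization and its serine proteases 2 rose, and 3 adjusted over the list alone, where dopa decarboxylase (OFAS008740), which makes dopamine from DOPA, was added. That list ranked up with a camera adjusted p of 6.4e-11, with adjusted p = 0.00871 with an estimated correlation, but adjusted p = 0.0701 with an estimated correlation and the replicate block, so the call was lost in the paired version. Dopa decarboxylase was at 28.1 ± 4.93 against 13.7 ± 3.22 CPM, with an adjusted p of 0.0755, and 0.00683 with the block, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 3 wound repair genes 1 rose, Tyrosine 3-monooxygenase, and adjusted over the list alone 2 were higher and 1 lower, namely Annulin (OFAS003693), a transglutaminase, at a log2 fold change of -0.94. The list's camera adjusted p was 0.00842, adjusted p = 0.0992 with an estimated correlation and 0.0775 with the block. Its 2 higher members, Tyrosine 3-monooxygenase and dopa decarboxylase, are also on the melanization list, so it adds no separate evidence of a rise.

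Further immune genes had no call in edgeR's fit without the block and passed with it. Thioester-containing protein (OFAS018551), a complement-like protein, was at 10.4 ± 0.959 CPM in septic and 5.62 ± 1.06 CPM in naive eggs. Peptidoglycan Recognition Protein (OFAS001578), of a family that binds bacterial cell walls, was at 13.7 ± 6.83 against 4.04 ± 0.827 CPM. Toll1 (OFAS011521), a receptor of the Toll pathway, was at 935 ± 76.9 against 717 ± 40.8 CPM, and cactus (OFAS007860), the inhibitor inside that pathway, at 97.4 ± 10.6 against 66.3 ± 13.6 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment their adjusted p was 0.0681, 0.251, 0.373 and 1 in the same order, and 0.00376, 0.00717, 0.00376 and 0.0345 with the replicate block. DESeq2 without the block called the first 3 and not cactus, with Benjamini-Hochberg adjusted p-values of 0.00151, 1.9e-04 and 0.0229, and over all alternatives the highest was 1, 0.9497, 1 and 1. Adjusted over the list alone, 1 of 11 lectins, thioester proteins and galectins, 1 of 3 recognition proteins and 1 of 17 Toll pathway genes was higher, against 0 over all genes in each list. The first of these lists ranked up with a camera adjusted p of 0.0243, adjusted p = 0.125 with an estimated correlation and 0.0775 with the block, and it was lost without naive replicate 1 or 3 or septic replicate 3, at up to 0.291. With fry that list's adjusted p was 0.0752. Recognition and Toll lists had camera adjusted p-values of 0.605 and 0.324. With the block, counts adjusted over the list alone went from 4 to 6 higher for antimicrobial peptides, 1 to 3 for lectins, 1 to 2 for Toll, from 2 to 5 higher and 0 to 5 lower for cuticle from 0 to 2 lower for serosa markers and from 13 to 14 higher for the models edited by the authors. The block also called Cytochrome P450 (OFAS005557), of a family of oxidases, (log2 fold change 1.47 without the block), Cuticle Protein RR-2 25 (OFAS010387) at a blocked log2 fold change of 0.70 and Cuticle protein Unclassified 11 (OFAS007228) at -0.51, with blocked adjusted p-values of 0.0269, 0.0128 and 0.0119 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

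Most other immune, stress and cell type genes had no call in septic against naive eggs. Markers of the serosa and amnion, the membranes around the embryo, ranked lower as a list of 7 with a camera adjusted p of 0.0243 and 0.00239 with the block, but adjusted p = 0.513 with an estimated correlation, and the call was lost without naive replicate 2 or 3 or septic replicate 1 or 2, at up to 0.317. With fry the list's adjusted p was 0.590. Over all genes and adjusted over the list alone 0 of its members were called. Its 7 members include Dorsocross as separate models, named part 1 of 4 to part 4 of 4, which camera counted as separate genes. The homeobox gene zerknuellt (OFAS000840), active in the serosa of insects, was at 64.4 ± 13.7 against 82.9 ± 15.6 CPM, with an adjusted p of 1, and 0.0199 with the block, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Hexamerin (OFAS014551), a storage protein and the only tested marker of yolk and fat body, was at 319 ± 85.7 against 528 ± 103 CPM. Its list has no other tested member, so adjusting over the list alone changes nothing. It was lower only at an unadjusted p under 0.05. Over all genes its adjusted p was 0.831 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The tested markers of blood cells (6), muscle (3) and the nervous system (5) held 0 calls, also adjusted over the lists alone, with camera adjusted p-values of 0.929, 0.673 and 0.605. Prophenoloxidase (OFAS000034), the blood enzyme of melanization, was at 4.84 ± 0.614 against 4.21 ± 0.283 CPM.

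Lists of the Imd (10), JAK-STAT (4) and JNK (4) pathways, phagocytosis and scavenger receptors (3), reactive oxygen and detoxification (28), RNA interference (10), heat shock (14), developmental patterning (23) and ribosomal proteins (11) held 0 calls among the tested members given in parentheses, also adjusted over each list alone. Their camera adjusted p-values ran from 0.395 for JAK-STAT to 0.903 for phagocytosis, and it was 0.605 for Imd, JNK and heat shock, 0.673 for reactive oxygen and patterning, and 0.757 for RNA interference and ribosomal proteins. The phagocytosis list holds hemocytin part 4 of 5 and part 1 of 5, models of the same gene by name, which camera counted as separate genes. Hemocytin also matches the pattern of the blood cell list. Of 53 tested cuticle and chitin genes 0 were called over all genes and 2 were higher adjusted over the list alone, with a camera adjusted p of 0.605. Lysozymes (2 tested) and cell death (1 tested) were too few for a list test and held 0 calls. The most abundant I-type lysozyme (OFAS015457), an enzyme that breaks bacterial cell walls, was at 103 ± 13.97 against 98.7 ± 13.1 CPM, and beta-1,3-glucan recognition protein (OFAS011838) at 85.6 ± 5.64 against 88.7 ± 10.1 CPM. Heat shock protein 90-2 (OFAS004736) was at 6123 ± 138 against 6019 ± 177 CPM, C-type lectin (OFAS008425) at 522 ± 20.6 against 521 ± 52.0 CPM, and hunchback (OFAS018348), a patterning gene, at 237 ± 27.7 against 236 ± 43.8 CPM. Of 43 tested models edited by the authors 8 rose, and 13 adjusted over the list alone, or 13 over all genes with the block, with a camera adjusted p of 4.9e-14, adjusted p = 0.0185 with an estimated correlation and adjusted p = 0.171 with an estimated correlation and the block, but the authors chose these models in this study, so the count is not independent evidence.

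Sterile against naive eggs addresses what the wound alone does. Tyrosine 3-monooxygenase and laccase 1 rose here too: the former stood at 12.2 ± 2.13 CPM (SD, n = 3) in sterile and 1.05 ± 0.267 CPM in naive eggs, and the latter at 4.38 ± 0.194 against 0.749 ± 0.0993 CPM. Of the antimicrobial peptide models, 0 of 9 were called, and Defensin-2 like (OFAS005103) had 1, 1 and 7 reads in sterile replicates 1 to 3. Drosophila Integral Protein rose from 0.850 ± 0.169 to 3.41 ± 0.648 CPM. The unnamed genes with the largest rise were OFAS011944 (4 exons at 77963 to 98879 of scaffold 737), at 11.03 ± 4.45 against 0.776 ± 0.509 CPM, and OFAS006190 (6 exons at 278820 to 298123 of scaffold 310), at 4.76 ± 0.874 against 0.320 ± 0.203 CPM.

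The log2 fold changes were 3.52 (SE 0.23) for Tyrosine 3-monooxygenase and 2.52 (SE 0.20) for laccase 1, with an adjusted p of 0.00132 and 0.00253 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and both calls held without any single library. For Drosophila Integral Protein, OFAS011944 and OFAS006190 the same Benjamini-Hochberg adjusted edgeR test gave 0.0347, 0.0343 and 0.0170. Drosophila Integral Protein lost its call without naive replicate 1, 2 or 3, sterile replicate 1, 2 or 3, or septic replicate 1 or 3, at up to 0.173. OFAS011944 lost it without naive replicate 1, 2 or 3, sterile replicate 1 or 3, or septic replicate 1 or 2, at up to 0.165, and OFAS006190 without naive replicate 1 or 3 or sterile replicate 1, at up to 0.0757. All 3 lost it with only the 6 samples compared, Drosophila Integral Protein and OFAS011944 also with glmTreat, and the former with replicates 1 and 2 alone. In all, 21 genes were higher, by at least 2.40-fold, and 0 were lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 423 were higher and 351 lower, together more than the 661 that chance alone gives. The shortfall seen for septic against naive eggs was thus absent here, in the same fit. DESeq2 called 64 higher and 15 lower, and edgeR with the replicate block 87 higher and 39 lower, all 21 among them. The count of 21 fell to 2, 12 and 6 without naive replicate 1, 2 or 3, to 3, 11 and 12 without sterile replicate 1, 2 or 3, and to 11 and 12 without septic replicate 1 or 2. It was 4 with only the 6 samples compared and 53 with replicates 1 and 2 alone, a fit chosen after the data were seen. Of the 21 genes, 18 had no name.

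Melanization had the smallest p of all lists after sterile injury. Of its 7 tested genes 2 rose, and 3 adjusted over the list alone, with a camera adjusted p of 1.3e-06 and adjusted p = 0.0296 with an estimated correlation. With an estimated correlation and the replicate block its adjusted p = 0.198, so the call was lost in the paired version. Of 3 wound repair genes 1 rose, with 2 higher and 1 lower (Annulin, log2 fold change -0.52) adjusted over the list alone, a camera adjusted p of 0.0130 and adjusted p = 0.164 with an estimated correlation. The adjusted p was 0.0834 with the block and 0.0963 without sterile replicate 3. Its 2 higher members are again Tyrosine 3-monooxygenase and dopa decarboxylase of the melanization list. Of 9 antimicrobial peptides 0 were called, also adjusted over the list alone, while the list's camera adjusted p was 0.0468, adjusted p = 0.644 with an estimated correlation. That call was lost with DESeq2's size factors (0.0659) or library totals (0.0626), and without naive replicate 1 or 2, sterile replicate 3, or any septic library, at up to 0.709. With fry the list's adjusted p was 0.630. Of 11 lectins, thioester proteins and galectins 0 were called and 1 was higher adjusted over the list alone, with a camera adjusted p of 0.0262, adjusted p = 0.164 with an estimated correlation, 0.0834 with the block, and 0.0501 to 0.0955 without naive replicate 1 or 3, sterile replicate 1 or 3, or septic replicate 3. With fry that list's adjusted p was 0.0512.

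Heat shock and ribosomal protein lists ranked lower in sterile than in naive eggs, by small amounts and uncertainly. Heat shock had 14 tested members, with 0 called and 1 lower adjusted over the list alone, lethal 2 essential for life (OFAS011624), a small heat shock protein, at 58.0 ± 2.69 against 68.5 ± 1.49 CPM. Its camera adjusted p was 0.0262, adjusted p = 0.177 with an estimated correlation, and lost without any one library other than sterile replicate 2, at up to 0.251. Ribosomal proteins had 11 members and 0 calls, also adjusted over the list alone, a camera adjusted p of 0.0440 and adjusted p = 0.612 with an estimated correlation, 0.0834 with the block, 0.0596 with DESeq2's size factors, and up to 0.455 without any one library other than naive replicate 3 and sterile replicate 2. With fry the ribosomal list's adjusted p was 0.292. Of 43 models edited by the authors, a list that is not independent evidence, 3 rose and 7 adjusted over the list alone, with a camera adjusted p of 4.1e-04 and adjusted p = 0.164 with an estimated correlation. With fry the edited list's adjusted p was 0.0512. The Toll pathway list had a camera adjusted p of 0.0619, and 0.00896 with the block, but adjusted p = 0.177 with an estimated correlation and 0.390 with an estimated correlation and the block. Of its 17 members 0 were called and 2, Toll1 and cactus, were higher adjusted over the list alone. The lists of recognition proteins (0 called, 1 higher adjusted over the list alone) and cuticle (0 called, 2 higher and 1 lower) had camera adjusted p-values of 0.228 and 0.832. Hexamerin, the only tested member of its list, was at 371 ± 73.3 against 528 ± 103 CPM. Adjusting over a list with a single tested member changes nothing, so it was lower only at an unadjusted p under 0.05. It was not called over all genes with or without the block. The other lists held 0 calls, also adjusted over each list alone, with camera adjusted p-values of 0.228 for RNA interference, 0.323 for JNK, 0.354 for reactive oxygen and for serosa markers, 0.423 for Imd and for phagocytosis, 0.498 for blood cells, 0.611 for the nervous system, 0.775 for patterning, 0.901 for muscle and 0.952 for JAK-STAT.

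With the replicate block, sterile injury also called Thioester-containing protein (11.2 ± 1.18 against 5.62 ± 1.06 CPM), Peptidoglycan Recognition Protein OFAS001578 (12.5 ± 4.70 against 4.04 ± 0.827 CPM), dopa decarboxylase (25.2 ± 1.97 against 13.7 ± 3.22 CPM), cactus (119 ± 34.9 against 66.3 ± 13.6 CPM) and Toll1 (931 ± 115 against 717 ± 40.8 CPM). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment their blocked adjusted p was 0.00224, 0.0105, 0.0177, 0.00339 and 0.00465. Without the block it was 0.0535, 0.313, 0.208, 0.437 and 0.348 in that Benjamini-Hochberg adjusted edgeR test. Defensin (OFAS008937) and the cotransporter rose by 1.12 and 1.64 on the log2 scale in the paired fit, with an adjusted p of 0.0368 and 0.00432 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Named genes lower in the paired fit included zerknuellt at -0.32, the patterning gene sloppy paired (OFAS008429) at -0.43, Fatty acid desaturase-putative (OFAS000818) at -0.61, Cuticle Protein CPAP1 4 (OFAS002278) at -0.34, Cuticle protein Unclassified 11 at -0.59 and Cuticle protein Unclassified 6 (OFAS006270) at -0.84, all log2 fold changes. Cuticle Protein RR-2 25 rose by 0.73 and Male-specific lethal 1-like protein (OFAS006865) by 1.17 in that fit. With the block, counts adjusted over the list alone went from 0 to 4 higher for antimicrobial peptides, 2 to 5 for Toll, 3 to 4 for melanization, and 0 to 1 for JAK-STAT and for blood cells. They went from 0 to 1 lower for serosa markers, from 1 higher to 2 higher and 1 lower for lectins, from 2 higher and 1 lower to 4 and 6 for cuticle, and from 7 higher to 13 higher and 1 lower for the edited models, of which 7 instead of 3 passed over all genes. In simulations of this comparison 17 of 203 calls of the paired fit were false. Without the block 3 of 159 were false, on counts simulated without a replicate effect.

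Septic against sterile eggs addresses what the bacteria add to the wound, and the named genes called were antimicrobial peptides. Defensin-2 Like (OFAS005105) was at 52.0 ± 15.5 CPM (SD, n = 3) in septic and 0.114 ± 0.137 CPM in sterile eggs, Defensin-2 like (OFAS005103) at 50.7 ± 13.8 against 0.201 ± 0.228 CPM, and Riptocin at 47.2 ± 35.5 against 0.288 ± 0.326 CPM. Their log2 fold changes were 8.73 (SE 0.49), 7.90 (SE 0.42) and 7.28 (SE 0.74), with adjusted p-values of 1.4e-04, 1.4e-04 and 0.00586 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Riptocin lost its call without sterile replicate 1 (0.0884) or 2 (0.0594) and with only the 6 samples compared (0.0785) in that Benjamini-Hochberg adjusted edgeR test. Unnamed OFAS013883 was at least 591-fold higher, and OFAS013885, with 1 sterile read, had a ratio of 2225 (95% interval 399 to 87942). Their adjusted p was 0.00586 and 0.00188 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and OFAS013885 lost its call without sterile replicate 1, at 0.0884.

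In all, 10 genes were higher in septic than in sterile eggs, by at least 3.08-fold, and 0 were lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05, 213 were higher and 187 lower, together fewer than the 661 that chance alone gives. DESeq2 called 15 higher and 1 lower, and the replicate block 18 higher and 2 lower, all 10 among them. The count of 10 fell to 5 without sterile replicate 1. With replicates 1 and 2 alone, a fit chosen after the data were seen, 13 were higher and 9 lower. Tyrosine 3-monooxygenase and laccase 1 were higher by 0.78 and 1.03 on the log2 scale in the paired fit, each with an adjusted p of 0.0209, against 0.996 and 0.0718 without the block, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Defensin OFAS005104 was at least 29.4-fold higher than in sterile eggs and the unknown secreted protein OFAS012858 higher by 3.43 on the log2 scale, with blocked adjusted p-values of 0.0226 and 0.0382 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

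Of 9 antimicrobial peptides 3 were higher in septic than in sterile eggs, and 4 adjusted over the list alone, with a camera adjusted p of 9.8e-08 and adjusted p = 0.365 with an estimated correlation. The list's median log2 fold change was -0.12 while its mean was 3.40, or 3.07 with Defensin OFAS005104 at its bound, so the median and the test had opposite signs. Of 7 melanization genes 0 were called and 2 were higher adjusted over the list alone, with a camera adjusted p of 0.00780, adjusted p = 0.346 with an estimated correlation, and 0.0909 and 0.0670 without sterile replicate 3 or septic replicate 2. Of 11 ribosomal proteins 0 were called, also adjusted over the list alone, with a camera adjusted p of 0.00780, adjusted p = 0.698 with an estimated correlation, and up to 0.158 without sterile replicate 1 or septic replicate 1 or 3. With fry the ribosomal list's adjusted p was 0.281. Of 43 models edited by the authors, not independent evidence, 5 were higher and 6 adjusted over the list alone, with a camera adjusted p of 0.00239, adjusted p = 0.365 with an estimated correlation and 0.0569 without septic replicate 3. Of 3 wound repair genes 0 were called and 1 was higher adjusted over the list alone, with a camera adjusted p of 0.665. With the block, counts lower adjusted over the list alone went from 0 to 1 for lectins and for phagocytosis, 0 to 2 for blood cells and 0 to 3 for the edited models. All other lists held 0 calls without the block, also adjusted over each list alone, with camera adjusted p-values from 0.0674 for heat shock to 0.879 for the nervous system.

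The responses to both injuries shared Tyrosine 3-monooxygenase, laccase 1 and Drosophila Integral Protein among 18 genes called higher in both, and 0 genes were lower in both by edgeR's quasi-likelihood test. Independent lists of these sizes would share 0.0603 genes. In 20 simulations of unchanged groups, with simulated naive libraries common to both comparisons, 0 genes were shared on average and 0 at most. With the block, 58 genes were higher and 8 lower in both, where independent lists would share 0.526 and 0.0442. The simulations with the block shared at most 2 and 1, and DESeq2 gave 48 and 5. A simulation called at most 2 genes in either comparison without the block and at most 8 with it. Their small overlap follows from so few calls and says little about lists of the observed sizes. The 3 naive libraries cannot be split into parts of 2, so the share of the excess that comes from the shared controls is not known. Across genes, which are not independent replicates, the log2 fold changes of both injuries correlated at 0.523 against 0.495 simulated, with a covariance of 0.0597 against 0.0324. With the replicate block in fit and simulation the correlation was 0.535 against 0.499 and the covariance 0.0606 against 0.0160. The 18 fell to 2 and 6 without naive replicate 1 or 3, to 3, 11 and 9 without sterile replicate 1, 2 or 3, and to 8 and 10 without septic replicate 1 or 3. It was 4 with only the 6 samples compared. Over all genes, 0 were called in all 3 comparisons.

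**Figure D2:**
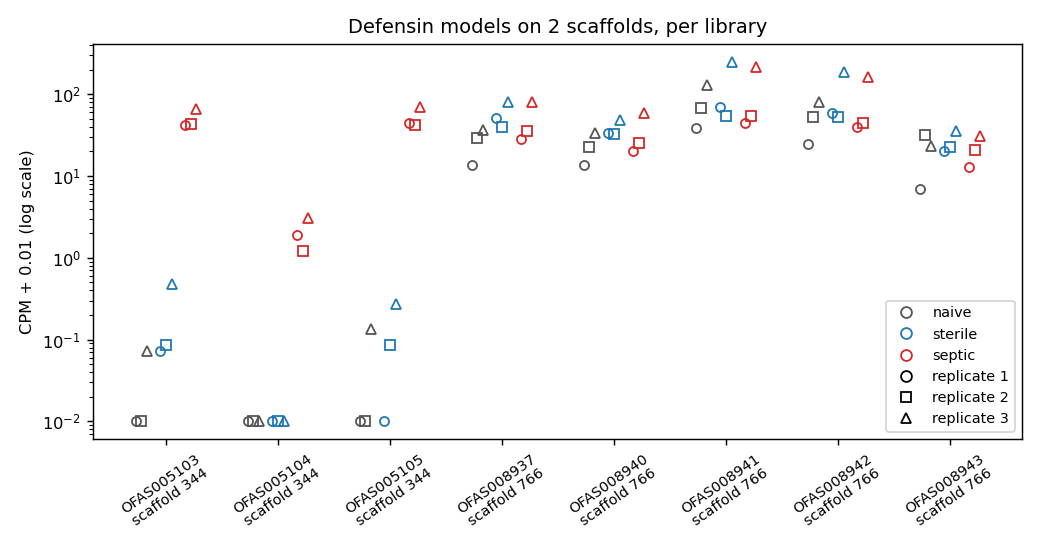
CPM plus 0.01 on a log scale for 8 defensin models, 3 on scaffold 344 and 5 on scaffold 766, in each of the 9 libraries. Colours mark naive, sterile and septic eggs and shapes mark replicates 1 to 3. OFAS005103 and OFAS005105 reach septic means of 50.7 and 52.0 CPM from near 0, while the models on scaffold 766 are well above 0 in all groups, with naive means from 20.6 to 78.3 CPM.

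The 5 tested defensins of scaffold 766 were already abundant in untreated eggs and held no call without the block. Defensin OFAS008941 was at 78.3 ± 45.7 CPM in naive, 124 ± 107 in sterile and 105 ± 96.4 in septic eggs (SD, n = 3), and Defensin OFAS008942 at 52.5 ± 27.9, 98.9 ± 74.6 and 82.7 ± 70.2 CPM. In both models replicate 3 was the highest library of every group.

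The authors' deposited table for septic against naive eggs holds 67 genes higher and 7 lower at their threshold of 0.05 on the adjusted p, and that for sterile against naive 65 and 15. In the authors' deposited table for septic eggs 37 of the 38 genes called here were among those higher, and in that for sterile eggs all 21 of 21. Of the blocked calls, 64 of 80 higher genes in septic and 58 of 87 in sterile eggs were also higher in the authors' deposited table, and 7 and 15 were lower there too. Defensin OFAS005104, dopa decarboxylase, Thioester-containing protein, Peptidoglycan Recognition Protein OFAS001578 and Toll1, without a call in edgeR's fit without the block, passed in the DESeq2 fit run here and in the authors' deposited table for septic eggs. Both are DESeq2 results from the same libraries, so they are not independent of each other. For Toll1 the authors' deposited table gives a log2 fold change of 0.38 with a DESeq2 adjusted p (Benjamini-Hochberg) of 0.0208 in sterile eggs.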

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

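The tests of antimicrobial models under the count filter, of chance placement and of fold changes on scaffold 703 below were chosen after the result was seen. Among 177 models of the gene lists that were too rare to be tested, 4 had at least 10 reads in an injured group and each of its libraries above every naive library in CPM, a signal in data that the comparisons did not use, and no test of chance was made. Hemiptericin (OFAS018152), an antimicrobial peptide by its list, had 33 reads in septic, 1 in sterile and 1 in naive eggs, of which septic replicate 3 held 26. Defensin (OFAS008569) had 21 reads in sterile, 6 in naive and 8 in septic eggs. Cuticle Protein RR-2 6 (OFAS001698) had 28 reads in sterile, 11 in naive and 12 in septic eggs. A cactus-like ANK protein (OFAS027198) had 11 reads in septic, 0 in naive and 2 in sterile eggs.

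Most antimicrobial peptide models stayed at low counts or without a call, and reads lost between close copies were weighed against a true lack of response. The 17 models without a call held 11852 septic, 15409 sterile and 9269 naive reads, and 5 of them had over 10 CPM. The ratio of septic to naive was 1.35 (95% interval 1.31 to 1.38, counting error only). By library they summed to 148, 182 and 556 CPM in septic and 236, 202 and 597 CPM in sterile replicates 1 to 3. The naive libraries, at 97.7, 204 and 303 CPM, overlapped with these, so the narrow interval is no sign of a rise after infection. The 11 models under the count filter held 63 septic and 8 naive reads, a ratio of 8.29 (3.96 to 20.03), 33 of the septic reads in Hemiptericin OFAS018152. Pooled they were at 0.726, 0.736 and 3.29 CPM in septic, 0.566, 0.609 and 0.663 CPM in sterile and 0.171, 0.127 and 0.247 CPM in naive replicates 1 to 3, so septic replicate 3 held most of the excess over naive eggs, and of the 27 sterile reads 21 were in Defensin OFAS008569. Both tests leave the loss of shared reads open, since reads that fit several copies are absent from the counts, and a response of single rare models to injury remains open beside it.

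Genes higher in septic than in naive eggs lay next to each other more often than random genes did. Among the 38 genes, 5 pairs were neighbours, where 10000 random sets held 0.0706 pairs on average and 2 at most, which argues against chance placement. The pairs were OFAS013883 with OFAS013884 and OFAS013884 with OFAS013885 on scaffold 1289, OFAS007675 with OFAS007676 on scaffold 703, OFAS011944 with OFAS011945 on scaffold 737, and OFAS009139 with OFAS009140 on scaffold 831. The log2 fold changes on scaffold 703, 5.23 (SE 0.47) and 2.07 (SE 0.29), differed by 3.17 (SE 0.55), which argues against 1 transcript split over both models as the whole cause of that pair. With 1 pair, that on scaffold 831, on opposite strands, a split transcript remains open for the other 3, and clusters of related genes that respond to injury, the biological alternative, were not tested.

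Regrouping the libraries gave values for the counts of called genes. With 3 against 3 libraries there are 10 splits, so no share under 0.05 can be reached. For septic against naive eggs the real split gave 38 genes and the highest other split 0, and for septic against sterile eggs 10 and 0. For sterile against naive eggs the real split gave 21 genes, and the split that set naive replicate 1, naive replicate 3 and sterile replicate 3 against the rest gave 257. With the replicate block, septic against sterile eggs gave 20 genes in the real split and 111 in the split of sterile replicates 1 and 2 with septic replicate 3 against the rest, while the other 2 comparisons gave 95 and 126 in the real split. The block was run on 3 other splits of each comparison, and in those 2 comparisons they gave 0.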

How the results depend on the processing

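The fit of replicates 1 and 2 alone and the list test with block and estimated correlation were chosen after the result was seen. All genes called without the block kept their call with it, and it changed no other call than those counted or given beside the results. DESeq2 kept 37 of 38, 21 of 21 and 10 of 10 calls for septic against naive, sterile against naive and septic against sterile eggs. Over the alternatives, the 37 genes named for septic against naive eggs kept direction and side of the threshold in 604 fits, lost a call in 30, gained 1 in 20 and reversed in 48. For the 20 genes of sterile against naive these counts were 326, 24, 30 and 0, and for the 9 of septic against sterile 158, 4, 8 and 0. Depth limits the rarest models, and 13224 of 19793 models had enough reads to be tested. The cause was not tested for any value below, except that a fold threshold leaves fewer calls by construction. Fewer samples left fewer calls in some fits and more in others.

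Genes higher in septic than in naive eggs (38) numbered 67 with DESeq2, 80 with the block, 23 with glmTreat and 18 to 37 without single libraries. Genes lower (0) numbered 7, 15 with the block, 3 with replicates 1 and 2 alone and 0 to 1 without single libraries. Genes higher in sterile than in naive eggs (21) numbered 35 without the filter, 64 with DESeq2, 4 with the 6 samples compared, 87 with the block, 6 with glmTreat, 53 with replicates 1 and 2 alone and 2 to 16 without single libraries. Genes lower (0) numbered 1 with upper-quartile factors, 2 without the filter, 15 with DESeq2, 39 with the block, 7 with replicates 1 and 2 alone and 0 to 1 without single libraries. For septic against sterile eggs, genes higher (10) numbered 18 with the block and 5 to 11 without single libraries, and genes lower (0) 1 with DESeq2, 2 with the block and 9 with replicates 1 and 2 alone.

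Genes higher in both injuries (18) numbered 48 with DESeq2, 4 with the 6 samples compared, 58 with the block, 5 with glmTreat and 2 to 12 without single libraries. Genes lower in both (0) numbered 5 with DESeq2, 8 with the block and 3 with replicates 1 and 2 alone. The lists past the threshold fell from 6 to 2 for septic against naive, from 7 to 1 for sterile against naive and from 4 to 0 for septic against sterile with an estimated correlation, to 0 in each with the block added, and to 3 for sterile against naive with fry. Without single libraries they numbered 4 to 6, 2 to 7 and 2 to 4. At 2-fold or more, the genes lower in the authors' deposited table went from 7 to 0 for septic and from 15 to 1 for sterile eggs.

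Genes without a call and with log2 fold changes near 0 in septic against naive eggs changed sign. With upper-quartile factors Bendless (OFAS010600) was at -0.0042, C-type lectin (OFAS008425) at -0.0069, Caspase-1 (OFAS015922) at -0.0096, tropomyosin1-partial (OFAS025078) at -0.0065 and ribosomal protein S6 (OFAS008704) at -0.0030. With replicates 1 and 2 alone stress-activated protein kinase JNK (OFAS016451) was at 0.0136, C-type lectin at -0.0371, hunchback (OFAS018348) at -0.0125 and ribosomal protein S6 at -0.0210. C-type lectin was at -0.0014 without the filter and at -0.0020 with the 1 CPM filter. Caspase-1 was at -0.00058 with DESeq2's size factors, -0.00095 with library totals, -0.0026 without the filter, -0.0031 with the 1 CPM filter and -0.0011 with DESeq2, and tropomyosin1-partial, whose exons are shared with another isoform, at -0.00019 with the 1 CPM filter.

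Without single libraries the log2 fold change ran from -0.0171 to 0.0352 for Bendless, -0.0561 to 0.0814 for C-type lectin, -0.0442 to 0.0710 for Caspase-1, -0.0014 to 0.0448 for Heat shock protein 90-2 (OFAS004736), -0.0398 to 0.163 for I-type lysozyme (OFAS015457), -0.0263 to 0.0398 for Thioredoxin reductase 1, -0.141 to 0.0222 for beta-1,3-glucan recognition protein (OFAS011838), -0.440 to 0.721 for hemocytin part 4, -0.104 to 0.160 for hunchback, -0.0577 to 0.0296 for ELAV-like protein 3, -0.0106 to 0.0279 for ribosomal protein S6, -0.0600 to 0.0440 for JNK and -0.0328 to 0.0516 for tropomyosin1-partial.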

Other observations

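Replicate 3 stood apart in all groups, and antimicrobial peptides were among its higher genes. Defensin OFAS008941 was at 55.1 CPM on average in replicates 1 and 2 and at 197 CPM in replicate 3, with 128, 248 and 216 CPM in replicate 3 of naive, sterile and septic eggs. Defensin OFAS008942 was at 45.5 and 143 CPM, and Riptocin at 9.07 and 29.8 CPM. Riptocin's reads were almost all from septic eggs, at 26.7 and 88.2 CPM, against 0.373 and 0.555 CPM in naive and 0.101 and 0.663 CPM in sterile eggs. Superoxide dismutase (OFAS016914), which removes superoxide, rose from 37.5 to 76.9 CPM, and myoglianin (OFAS016710), a growth factor of the TGF-beta family, from 6.22 to 13.1 CPM. Of 9 tested antimicrobial peptides 7 were higher in replicate 3, with a camera adjusted p of 2.7e-05 and adjusted p = 0.455 with an estimated correlation. Among the 7 were Riptocin and the Defensin-2 models OFAS005103 and OFAS005105, whose rise in CPM rests almost wholly on septic replicate 3. There OFAS005103 and OFAS005105 were at 66.7 and 69.9 CPM, against 0.464 and 0.265 CPM in sterile replicate 3. Of 7 marker models of serosa and amnion, with the parts of Dorsocross counted separately, 3 were higher. The list's camera adjusted p was 0.0149, and adjusted p = 0.455 with an estimated correlation.

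In replicate 3 against replicates 1 and 2, Ankyrin2 (OFAS025007) fell from 78.9 to 9.67 CPM, mothers against dpp 1 (OFAS025016), of a family that carries TGF-beta signals, from 69.3 to 12.6 CPM, and Methoprene tolerant part 1 (OFAS025330), a juvenile hormone receptor, from 26.4 to 3.74 CPM. Pebbled (OFAS006632) fell from 18.1 to 2.81 CPM and oo18 RNA-binding protein (OFAS001872) from 5.71 to 0.704 CPM. In all, 945 genes were higher and 1324 lower in replicate 3 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in a comparison chosen after the data were seen.

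The test of library depth was chosen after the result was seen, and those of transcript length and age were written before it was run. Replicate 3 had the highest total in 1 of 3 groups, which argues against depth. Spearman's rho of its log2 fold changes with exon length was -0.0440, which argues against a length bias. A different age within the collection window could not be decided: the smaller camera adjusted p of the cuticle and patterning lists was 0.211. The prediction written for that test was wrong in its negative part, because 5 cuticle genes were higher and 6 lower, and 4 patterning genes higher and 4 lower, which a test for 1 direction cannot see. No biological explanation other than age was tested, since the labels do not say what a replicate number stands for.

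C-type lysozyme (OFAS013226), an enzyme that breaks bacterial cell walls, had 22 reads in septic replicate 3, 2 in sterile replicate 3, and 1 each in naive replicate 2 and septic replicate 2.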
